A study of Mus musculus with 48 samples.

How the data were processed

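Lacrimal and meibomian glands of aromatase knockout and wild type mice of both sexes were pooled, per the labels, from 5 to 8 mice into 3 pools for each of 8 groups. RNA was biotin-labelled from 2 µg with the CodeLink reagents, and each preparation was put on an Affymetrix and a CodeLink mouse array, 24 arrays of each type. The labels of the CodeLink arrays give Trizol and spin columns for lacrimal and only Trizol extractions for meibomian glands, while those of the Affymetrix arrays give Trizol and spin columns for both, so levels were not compared between glands, only effects within them. Each array is 1 pool.

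The Affymetrix table holds intensity values per probe set as deposited by the authors, and GCOS, the Affymetrix software, is named in the submitters' processing notes without a version or settings. The array medians show that these signals were not scaled to 1 level. The CodeLink array files hold, per the file headers, the intensity of each spot as its mean minus the median of its local background, and a value that is this intensity divided by 1 factor per array. The deposited CodeLink table matched those values within 0.1% for 99.8% of spots above 1. Detection calls of the Affymetrix arrays and scanner settings were not used here.

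The Affymetrix table has 22690 probe sets, of which 20393 name 1 gene, 691 name several and 1606 (7.08%) name none. Symbols were brought up to date through a RefSeq gene table of assembly GRCm38.p6 for 20364 probe sets, and this table was used only for names and for which genes neighbour each other. CodeLink array files hold 20287 spots, and 17440 are in the value table, of which 11377 name 1 gene. Probe sets with several genes or none were left out except in the alternative that tests every probe set. A gene was represented by the probe set or spot with the highest mean, which gave 12394 Affymetrix and 10956 CodeLink genes, 9168 of them on both types.

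Values were log2-transformed after adding a pseudocount, the 20th percentile of positive values (4.4 for Affymetrix, 0.2675 for CodeLink), and each array was centred on its median. Within each gland the top 60% of genes by mean were tested, 7436 genes, and 6577 genes for differences between glands. One linear model with 4 group means per gland, or 8 for differences between glands, was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 5%. The 12 comparisons were the knockout effect in each gland and sex, the sex difference in each gland and genotype, the difference of the knockout effects between the sexes in each gland, and that between the glands in each sex. Affymetrix was the main array type and CodeLink was fitted in the same way on its own. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 drew the figures. These settings, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined.

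Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of a comparison. No list passed 5% with an estimated correlation in any comparison, the smallest adjusted p being 0.0931 for endothelial genes between knockout sexes of the meibomian gland. Members were also adjusted over the list alone. Genes were named by rule as the sex chromosome genes, the 12 largest increases and 12 largest decreases that passed and had the same sign on CodeLink (6 and 6 for differences of effects), and up to 4 members with the smallest p of each list that passed camera. Where fewer than 10 genes passed, up to 6 genes per direction with an unadjusted p under 0.01 and a log2 difference of at least 1 were added and named as not passing. Genes with clone names were counted and not named, and the text names part of the genes the rule allows.

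Affymetrix folds are bounds where the mean signal of the lower group was under the pseudocount. Where a CodeLink spot had the flag G on no array of the lower group, the fold is a bound, for which each such value was raised to the lowest value with that flag on its array. The simulated unchanged groups were drawn around the wild type means with the measured spread of each gene, and the wild type arrays were divided in 6 ways so that the comparisons shared none. Replicate numbers link the array types: each Affymetrix array correlated best with the CodeLink array of its own number within its group for 22 of 24 arrays.

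The fits were tested on simulated data, 3 runs with 200 genes changed by known amounts among the 7436 or 6577 genes. Genes changed by 1 log2 unit were found for 68.2% in lacrimal females, 64.2% in lacrimal males, 58.2% between wild type and 60.7% between knockout lacrimal sexes, and 27.4% for the lacrimal difference of effects. In meibomian glands the shares were 92.5% in females, 90.5% in males, 92.0% and 94.5% between the sexes of wild types and knockouts, and 74.1% for the difference of effects, and between the glands 56.7% in females and 57.2% in males. Changes of 0.5 log2 units were found for 9.95 and 10.9% in lacrimal and 44.8 and 38.8% in meibomian females and males. Between 3.42 and 6.95% of calls fell on unchanged genes, none with the wrong sign. Such rates were not measured on the real arrays.

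The alternatives chosen then were quantile normalization, other pseudocounts (5th and 40th percentile), no filter or the top 40% of genes, every probe set on its own, no intensity trend, only the groups compared in the fit, the replicate number as a block, CodeLink alone, the mean of both array types, and leaving out each array in turn. Chosen after seeing the data were CodeLink with quantile normalization, the salivary marker score as a covariate in lacrimal glands, the meibomian fit less both Affymetrix arrays that stand apart (wild type female replicate 2 and knockout male replicate 2), the CodeLink fit less its array that stands apart (meibomian wild type female replicate 3) and the CodeLink fit with the replicate number as a block.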

Results

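Lacrimal and meibomian glands of homozygous aromatase knockout mice and of wild type mice of the same age were profiled in both sexes, to ask how loss of aromatase, the enzyme that turns androgens into estrogens, changes gene expression in each gland. The lacrimal gland secretes the watery layer of tears and the meibomian glands of the eyelids secrete the lipid layer. Each of the 8 groups of gland, genotype and sex held 3 pools of glands from 5 to 8 mice. Labelled RNA of every pool was put on an Affymetrix and on a CodeLink mouse array, 48 arrays in all. The median Affymetrix signal per array ran from 12.2 to 20.8 in lacrimal and from 35.5 to 84.05 in meibomian glands. Lacrimal arrays of knockout females had a lower median signal (12.9 ± 0.751, mean ± SD, n = 3) than those of wild type females (17.8 ± 2.07). On CodeLink, 35.9 to 47.5% of spots per lacrimal array and 51.9 to 62.6% per meibomian array carried the flag G, whose meaning the array files do not state. The number of arrays per group limits the precision of every value. Differences are given as log2 ± standard error from limma with 3 pools per group, with p-values adjusted over all genes tested, and CodeLink repeats the same RNA, so it adds no mice. Affymetrix folds were computed after adding a pseudocount and understate the change of dim genes.

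Sex chromosome genes matched the sex labels on the Affymetrix arrays. Xist, which is transcribed from the inactive X chromosome, was higher in females by 5.62 ± 0.33 in wild type and 5.19 ± 0.33 in knockout lacrimal glands, and by 6.53 ± 0.24 and 6.36 ± 0.24 in meibomian glands. The Y-linked gene Eif2s3y was higher in males, with differences of −5.35 ± 0.24, −4.66 ± 0.24, −6.14 ± 0.29 and −6.81 ± 0.29 in the same order. Y-linked Kdm5d differed by −2.34 ± 0.35 in wild type and −1.55 ± 0.35 in knockout lacrimal glands on Affymetrix, while its CodeLink spot did not separate the sexes. No probe with a single gene name stood for aromatase itself, so the targeted gene was not analysed here and the genotype labels have no check from it.

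The first principal component held 42.0% of the variance of the lacrimal arrays and ordered the groups from wild type females (−31.04 ± 0.18, mean ± SD, n = 3) through knockout females (−9.42 ± 6.66) and wild type males (10.93 ± 4.53) to knockout males (29.53 ± 3.03). Knockout females lay between wild type females and wild type males in every one of the 3 pools. Among meibomian arrays the first component held 32.9% and parted the sexes, with wild type females at −9.47 ± 5.30 and knockout females at −12.80 ± 4.09 against wild type males at 13.69 ± 3.74 and knockout males at 8.58 ± 2.26.

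Aromatase knockout raised a set of genes strongly in the lacrimal glands of females. Ly6f, a member of the Ly6 family of surface proteins held by a lipid anchor, rose 66.9-fold (6.06 ± 0.35, adjusted p = 4.43e-09). Cyp2j13, a cytochrome P450, rose 46.9-fold (5.55 ± 0.26, adjusted p = 2.36e-10), and its CodeLink spot, without the flag G in all 3 wild type pools, gave a rise of at least 38.2-fold. The zinc transporter gene Slc39a8 fell 5.45-fold (−2.44 ± 0.22, adjusted p = 1.79e-06), with a difference of −0.39 on CodeLink. Gdf5, which encodes a bone morphogenetic protein, fell 5.40-fold (−2.43 ± 0.39, adjusted p = 0.000937).

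Large increases in knockout females were also those of Cuzd1 (4.01 ± 0.43) and Mrap (3.68 ± 0.26), the first encoding a zymogen granule membrane protein and the second an accessory protein of melanocortin receptors. Other genes of enzymes and transporters that rose were Fmo5 (3.61 ± 0.27), B4galt6 (3.48 ± 0.22), St6galnac1 (2.90 ± 0.55), Slc27a2 (2.31 ± 0.18) and Pmvk (2.19 ± 0.27); B4galt6 makes lactosylceramide and St6galnac1 adds sialic acid to mucins. The growth factor gene Pgf (2.53 ± 0.30), the death receptor gene Fas (2.20 ± 0.31) and the replication factor gene Cdc45 (2.19 ± 0.32) rose as well. Decreases included Abcb1a (−1.92 ± 0.35) and Asgr1 (−1.65 ± 0.30), which encode a drug efflux pump and a subunit of the asialoglycoprotein receptor. Carboxypeptidase E (Cpe, −1.68 ± 0.33), cysteine dioxygenase (Cdo1, −1.55 ± 0.22) and the carbonyl reductases Cbr2 (−1.54 ± 0.20) and Dcxr (−1.52 ± 0.17) fell, as did Khdrbs3 (−1.64 ± 0.26), Ceacam10 (−1.50 ± 0.23), Tceal8 (−1.49 ± 0.23) and Ddr1 (−1.42 ± 0.28).

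Secreted proteins of the tear film leaned upward in knockout females, with 17 of 22 tested members positive and 4 rising over all genes, or 5 when adjusted over the list alone. This list also names Smr3a, Cst10 and Dcpp1, used below as salivary gland markers, whose levels varied between arrays of a group. Camera gave 3.26e-05 as adjusted p (0.216 with an estimated correlation). Prol1 (3.85 ± 0.57), Mup5 (2.16 ± 0.34), Wfdc12 (1.21 ± 0.28) and Prom2 (0.75 ± 0.19) rose, among them the proline-rich lacrimal protein gene Prol1, and the mean of the list was 0.55 on Affymetrix and 0.06 on CodeLink. In the list of cytokines and chemokines Il18 (1.20 ± 0.25) and Ccl8 (1.12 ± 0.29) rose out of 16 members, or 3 members when adjusted over the list alone. Camera gave 0.0108 as adjusted p (0.522 with an estimated correlation). Plasma cell genes Jchain (0.96 ± 0.18) and Igha (0.54 ± 0.14) rose, 2 of 10 members both over all genes and adjusted over the list alone. Camera gave 0.0114 as adjusted p (0.522 with an estimated correlation). After quantile normalization this list did not pass camera (adjusted p = 0.0879). Macrophage and dendritic cell genes had 18 of 25 positive differences but 0 passed, and 0 passed when adjusted over the list alone. Camera gave 0.0114 as adjusted p (0.869 with an estimated correlation). Heat shock genes leaned downward, where Hspa1b (−1.71 ± 0.43) was the 1 member of 14 to fall, also when adjusted over the list alone. Camera gave 0.0114 as adjusted p, and adjusted p = 0.736 with an estimated correlation. Of 22 fibroblast and matrix genes Sparc (−0.59 ± 0.16) fell, again 1 when adjusted over the list alone. Camera gave 0.0238 as adjusted p, and adjusted p = 0.734 with an estimated correlation. On CodeLink the tear protein (mean 0.06, adjusted p = 0.359) and macrophage (mean 0.14, adjusted p = 0.0582) lists did not pass camera.

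Across 7436 genes, 307 passed 5% in lacrimal glands of females, 152 higher and 155 lower in knockouts, and Ly6f, Cyp2j13 and 131 in all changed at least by a factor of 2. The balance depended on the processing, with 126 higher and 376 lower at the 40th percentile pseudocount and 209 higher and 146 lower after quantile normalization. Of the 204 of these genes also measured on CodeLink, 192 had the same sign there, and 149 genes passed on CodeLink by its own test. The count was 177 without replicate 2 and 151 without replicate 3 of the knockout females.

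In males the knockout raised a different group of lacrimal genes, several of them known from salivary glands. Ddc, the decarboxylase that makes dopamine and serotonin, rose 217-fold (7.76 ± 0.35, adjusted p = 8.42e-11) and at least 26.2-fold on CodeLink. Nmu, the gene of the peptide neuromedin U, rose at least 149.9-fold (7.23 ± 0.30, adjusted p = 3.58e-11) and at least 128-fold on CodeLink. The kallikrein gene Klk1b27 rose at least 143-fold (7.16 ± 0.43, adjusted p = 6.48e-09) and at least 34.0-fold on CodeLink. Bounds stand for Affymetrix signals under the pseudocount in the lower group and for CodeLink spots without the flag G in all 3 wild type pools. B4galt1, a galactosyltransferase of the Golgi, fell 9.85-fold (−3.30 ± 0.29, adjusted p = 2.03e-06).

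Further increases in knockout males were those of Klk1b24 (4.53 ± 0.29), Klk1b21 (3.95 ± 0.47), Smr2 (4.10 ± 0.41) and Tspan6 (3.60 ± 0.28), where Smr2 encodes a submaxillary gland protein regulated by androgens and differed by 0.59 on CodeLink without passing there. Across the kallikrein family 7 of 8 Klk1b genes were at least 1 log2 unit higher. Sult1e1, the sulfotransferase that inactivates estrogens, rose by 1.73 ± 0.27. Smaller increases were those of the acyl-CoA synthetase gene Acsbg1 (2.37 ± 0.36), the neuronal growth gene Dpysl3 (2.19 ± 0.21), the glutamyltransferase gene Ggt7 (1.84 ± 0.41) and the circadian gene Clock (1.79 ± 0.33). Decreases included the protease inhibitor gene Mug1 (−2.30 ± 0.35), the zinc finger gene Plagl1 (−1.87 ± 0.25), Shisa2 (−1.79 ± 0.33), Fxyd4 (−1.69 ± 0.41) and Asgr1 (−1.36 ± 0.30) and the DNA damage kinase gene Atm (−1.35 ± 0.24). Cmya5 (−1.34 ± 0.31), Folh1 (−1.26 ± 0.26), Nck2 (−1.15 ± 0.18), Cyp39a1 (−1.12 ± 0.19) and Pllp (−1.12 ± 0.23) fell too, Cyp39a1 being an oxysterol hydroxylase.

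**Figure D1:**
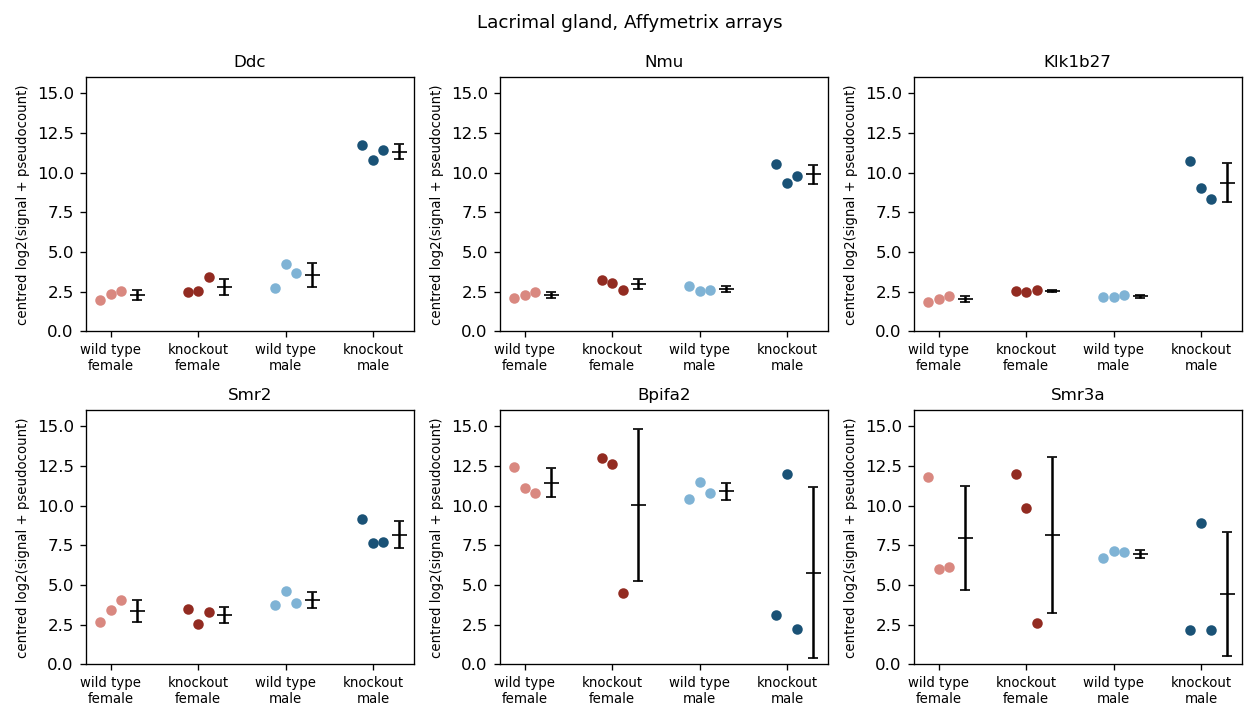
Centred log2(signal + pseudocount) of 4 genes raised in knockout male lacrimal glands (Ddc, Nmu, Klk1b27, Smr2) and of the salivary gland genes Bpifa2 and Smr3a on the Affymetrix lacrimal arrays, with each point 1 array and each bar the mean ± SD of 3 arrays. The 4 genes are high in knockout males alone, while Bpifa2 and Smr3a vary between the arrays of a group.

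The score of 6 salivary gland markers, among them Bpifa2 and Smr3a, was 4.84 ± 3.23 in knockout males and 6.62 ± 0.28 in wild type males (mean ± SD of log2 signal). For the 7 genes named above with a rise of at least 3 log2 units it was 9.11 ± 0.72 and 3.64 ± 0.25. Atm and Il18 lie among the 100 tested genes on either side of the aromatase gene.

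Some immune genes rose in lacrimal glands of knockout males. All 25 macrophage and dendritic cell genes tested had positive differences with a mean of 0.63, 4 passed over all genes (Lyz2 (0.94 ± 0.18), Fcgr2b (0.97 ± 0.21), Clec7a (1.07 ± 0.25) and Ms4a7 (0.81 ± 0.20)) and 16 when adjusted over the list alone. Camera gave 5.27e-16 as adjusted p (0.140 with an estimated correlation). Among 16 cytokines and chemokines 5 rose, with Il18 (1.68 ± 0.25), Ccl9 (1.13 ± 0.22), Ccl8 (1.35 ± 0.29) and Cxcl16 (1.10 ± 0.27) as examples, or 6 when adjusted over the list alone. Camera gave 5.00e-05 as adjusted p (0.140 with an estimated correlation). Oas1a (1.51 ± 0.30) was the 1 interferon-stimulated gene of 17 to rise, 1 when adjusted over the list alone. Camera gave 0.000959 as adjusted p (0.217 with an estimated correlation). H2-Aa (0.81 ± 0.19) rose among 8 class II antigen presentation genes, 3 of which passed when adjusted over the list alone. Camera gave 0.000959 as adjusted p (0.262 with an estimated correlation). Psmb10 (0.92 ± 0.23) rose among 10 class I genes, 2 of which passed when adjusted over the list alone. Camera gave 0.00395 as adjusted p (0.262 with an estimated correlation). Of 9 complement and acute phase genes lipocalin 2 (Lcn2, 1.96 ± 0.27) rose and 1 fell, or 3 and 1 when adjusted over the list alone. Camera gave 0.00395 as adjusted p (0.140 with an estimated correlation).

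Androgen-responsive genes of kidney and submandibular gland had a mean difference of 1.29 in knockout males, but only 7 of 12 were positive. 4 of them rose, the kallikreins Klk1b27 (7.16 ± 0.43), Klk1b24 (4.53 ± 0.29), Klk1b21 (3.95 ± 0.47) and Klk1b11 (1.60 ± 0.23), while 4 rose and 2 fell when adjusted over the list alone. Camera gave 0.000663 as adjusted p (0.140 with an estimated correlation). Matrix genes Postn (0.94 ± 0.17) and Mfap5 (1.12 ± 0.26) rose, 2 of 22 fibroblast genes over all genes and when adjusted over the list alone. Camera gave 0.0114 as adjusted p (0.413 with an estimated correlation). Of 26 chaperone and unfolded protein response genes 23 had negative differences and none passed, over all genes or adjusted over the list alone. Camera gave 0.00395 as adjusted p (0.568 with an estimated correlation). Among 8 adipocyte genes none passed over all genes and 1 fell when adjusted over the list alone. Camera gave 0.0114 as adjusted p (0.166 with an estimated correlation). On CodeLink the class I (mean 0.22, adjusted p = 0.199), chaperone (mean −0.15, adjusted p = 0.125), complement (mean 0.09, adjusted p = 0.458) and adipocyte (mean −0.22, adjusted p = 0.410) lists did not pass camera. Camera also placed cell cycle genes higher (adjusted p = 0.561 with an estimated correlation), which did not pass on CodeLink (adjusted p = 0.0534).

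In lacrimal glands of males 136 genes passed 5%, 85 higher and 51 lower in knockouts, from Ddc at the top to B4galt1 at the bottom. On CodeLink 91 of the 96 measured there had the same sign, and 61 genes passed. The count was 68 without replicate 1 and 84 without replicate 3 of the knockout males, and 61 without replicate 3 of the wild type males.

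The knockout effect differed between the sexes in the lacrimal gland. The difference, female minus male effect, was 6.54 ± 0.49 for Ly6f, 5.53 ± 0.61 for Cuzd1, 5.32 ± 0.37 for Cyp2j13 and 3.22 ± 0.31 for B4galt6, which rose in females, and 3.51 ± 0.42 for B4galt1 and 3.33 ± 0.49 for Mug1, which fell in males. It was −7.24 ± 0.50 for Ddc, −6.67 ± 0.61 for Klk1b27, −6.56 ± 0.43 for Nmu, −4.36 ± 0.58 for Smr2, −4.12 ± 0.66 for Klk1b21 and −4.08 ± 0.41 for Klk1b24, all raised in males.

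Tear protein genes leaned toward a more positive effect in females, with 18 of 22 members positive. Prol1 (3.53 ± 0.81) was the 1 member called higher and 1 was lower, also when adjusted over the list alone. Camera gave 0.00907 as adjusted p (0.412 with an estimated correlation). After quantile normalization the list did not pass (adjusted p = 0.252). Fibroblast and matrix genes leaned toward males (mean −0.51), where none passed over all genes and 5 when adjusted over the list alone. Camera gave 0.000463 as adjusted p (0.412 with an estimated correlation). Macrophage genes had a mean of −0.40, with none passing over all genes and 2 when adjusted over the list alone. Camera gave 0.00357 as adjusted p (0.622 with an estimated correlation). The kallikreins placed 3 androgen-responsive genes among those lower and 1 among those higher, or 4 and 1 when adjusted over the list alone. Camera gave 0.0399 as adjusted p (0.569 with an estimated correlation). Lcn2 (−2.02 ± 0.39) and ceruloplasmin (Cp, −1.57 ± 0.37) were the 2 complement and acute phase genes called lower, 2 when adjusted over the list alone. Camera gave 0.0407 as adjusted p (0.412 with an estimated correlation). Metallothionein 1 (Mt1, −1.41 ± 0.31) was the 1 oxidative stress gene called lower, while 1 was higher and 2 lower when adjusted over the list alone. Camera gave 0.0311 as adjusted p (0.622 with an estimated correlation). On CodeLink the tear protein (mean 0.00, adjusted p = 0.635), oxidative stress (mean −0.30, adjusted p = 0.0745) and complement (mean −0.40, adjusted p = 0.135) lists did not pass camera. Camera also placed chaperone and secretory pathway genes higher and heat shock and myoepithelial genes lower (smallest adjusted p = 0.622 with an estimated correlation). Those placed higher passed neither on CodeLink (adjusted p = 0.426 and 0.543) nor after quantile normalization.

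In all 123 genes passed 5% for a difference of the lacrimal effects, 68 positive and 55 negative, led by Ddc and Ly6f, and 56 positive and 97 negative at the 40th percentile pseudocount. The same sign was found on CodeLink for 76 of 81 genes, where 74 passed. No single array moved this count by over 1.5 times.

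Lacrimal glands of wild type females and males differed widely. The lipase-related gene Pnliprp1 was 364-fold higher in females (8.51 ± 1.01, adjusted p = 1.48e-05) and Asgr1 50.5-fold higher (5.66 ± 0.30, adjusted p = 8.48e-10). Cyp2j13 was 97.7-fold lower in females (−6.61 ± 0.26, adjusted p = 1.15e-11), Ly6f 46.2-fold lower (−5.53 ± 0.35, adjusted p = 4.18e-09) and Prol1 56.4-fold lower (−5.82 ± 0.57, adjusted p = 1.74e-06).

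Also higher in wild type females were Gdf5 (3.44 ± 0.39), Abcb1a (2.54 ± 0.35), Khdrbs3 (2.48 ± 0.26), Slc39a8 (2.42 ± 0.22) and Akr1c18 (2.64 ± 0.16), of which Akr1c18 encodes a hydroxysteroid dehydrogenase that inactivates progesterone, and Acot1 (2.36 ± 0.36), Tspan3 (2.29 ± 0.23), Arg2 (2.17 ± 0.45), Gdpd5 (2.17 ± 0.37) and Cryab (2.14 ± 0.22). Also lower in wild type females were Mrap (−4.30 ± 0.26), Fmo5 (−4.16 ± 0.27), Pgf (−3.92 ± 0.30), B4galt6 (−3.36 ± 0.22), Fut8 (−3.27 ± 0.32), Sgk3 (−3.21 ± 0.29), Slc27a2 (−3.03 ± 0.18), Fap (−2.87 ± 0.24) and Bok (−2.60 ± 0.23). The genes higher in females included 12 of 32 proteasome genes, Psmd11 (1.13 ± 0.16) and Psmd12 (0.71 ± 0.15) among them, or 14 when adjusted over the list alone. Camera gave 0.000694 as adjusted p (0.589 with an estimated correlation). Heat shock genes were all positive, 4 of 14 passed, including Hspa8 (1.62 ± 0.23) and Hspa1a (1.12 ± 0.33), and 6 passed when adjusted over the list alone. Camera gave 0.00443 as adjusted p (0.589 with an estimated correlation). The oxidative stress genes Gstm1 (1.14 ± 0.15), Gclm (1.23 ± 0.18) and Gsta3 (0.88 ± 0.15) were higher, 9 of 24 in all with 1 lower, or 10 and 1 when adjusted over the list alone. Camera gave 0.0372 as adjusted p (0.688 with an estimated correlation). For oxidative phosphorylation 12 of 59 genes were higher and 1 lower, or 20 and 1 when adjusted over the list alone. Camera gave 0.00143 as adjusted p (0.688 with an estimated correlation). The mean of 0.30 turned to −0.0415 on CodeLink. Lower in females were the chemokine gene Ccl8 (−2.10 ± 0.29) and the plasma cell genes Jchain (−0.94 ± 0.18), Igha (−0.64 ± 0.14) and Igk (−1.13 ± 0.31), 5 of 10 plasma cell genes in all with 1 higher, the same counts as adjusted over the list alone. Camera gave 0.00166 as adjusted p (0.589 with an estimated correlation). Tear protein genes had 4 of 22 members lower and 1 higher, with equal counts adjusted over the list alone. Camera gave 0.0159 as adjusted p (0.589 with an estimated correlation). After quantile normalization the tear protein and oxidative stress lists no longer passed camera (adjusted p = 0.149 and 0.0774), and the means shrank from 0.38 to 0.199 for the proteasome, from 0.34 to 0.211 for oxidative stress and to 0.129 for oxidative phosphorylation. On CodeLink the proteasome (mean 0.10, adjusted p = 0.280), oxidative stress (mean 0.08, adjusted p = 0.579), plasma cell (mean −0.66, adjusted p = 0.112) and tear protein (mean −0.28, adjusted p = 0.280) lists did not pass camera. Camera also placed cytokine and macrophage genes lower (smallest adjusted p = 0.589 with an estimated correlation). Neither passed on CodeLink (adjusted p = 0.280 and 0.113) or after quantile normalization.

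Counting all genes, 1063 passed 5% between the sexes of wild type lacrimal glands, 727 higher and 336 lower in females, and the median of all genes was shifted by 0.125. After quantile normalization the split was 494 higher and 527 lower, so the excess of genes higher in females depended on the scaling. On CodeLink 633 of 723 genes had the same sign, and 463 passed, 160 higher and 303 lower in females. The count was 670 without replicate 2 of the wild type females and 587 without replicate 2 of the wild type males.

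Most genes that rose in lacrimal glands of knockout females were genes that wild type males express more than wild type females. Of 152 genes raised in knockout females, Ly6f and Cyp2j13 among them, 130 (85.5%) were also higher in wild type males and none was higher in wild type females. Of 155 genes lowered, such as Gdf5 and Asgr1, 123 (79.4%) were higher in wild type females and none in wild type males. Independent lists of these sizes would share 6.87 and 15.2 genes. Both comparisons use the wild type female arrays, so part of the excess may come from them. Across genes the female knockout effect and the male-minus-female difference correlated at r = 0.738, against 0.218 simulated, with a covariance of 0.166 against 0.0354 simulated. Genes are not independent replicates here. The excess covariance was 57.0% of the variance of the sex difference across genes, less the part due to noise. This is a slope across genes, in which genes with large sex differences weigh most, and not a share of the genes. It was 50.2 to 65.7% with single arrays left out and 56.1% on CodeLink. With each comparison given its own wild type arrays, the correlation ran from 0.454 to 0.555 over 6 divisions on Affymetrix and from 0.315 to 0.540 on CodeLink.

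**Figure D2:**
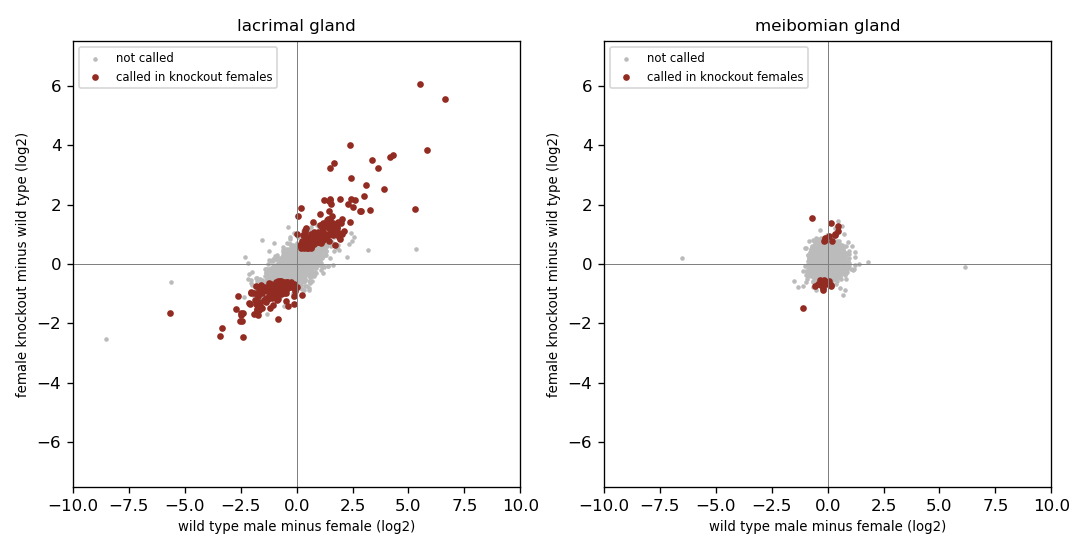
Log2 difference between wild type males and females (x axis, male minus female) against the log2 knockout effect in females (y axis, knockout minus wild type) for each gene of the lacrimal gland on Affymetrix, with genes that passed 5% for the knockout effect in red. Each point is 1 gene, and no red point that passed in both comparisons lies in the opposite quadrants.

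In males the same comparison gave a weaker relation by most measures. Of 85 genes raised in knockout males, 23 were higher in wild type males (3.84 for independent lists) and 8 higher in wild type females (8.31). Of 51 genes lowered, such as Asgr1 and Mug1, 19 were higher in wild type females (4.99) and 2 in wild type males (2.30). The correlation across genes was 0.0993 against −0.217 simulated, and the covariance 0.0212 against −0.0346 simulated. The slope was 24.3% (22.8 to 39.8% with single arrays left out), and 33.2% on CodeLink. With wild type arrays not shared the correlation ran from 0.114 to 0.261 on Affymetrix and from 0.140 to 0.403 on CodeLink, where the rank correlation, 0.140 to 0.512, was not below that of females, 0.0578 to 0.353. Knockouts of both sexes shared 8 raised genes, Il18 and Ccl8 among them (1.74 for independent lists), and 8 lowered genes, such as Asgr1 (1.06), while 2 and 2 genes went opposite ways (1.04 and 1.77).

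Between knockout females and males the lacrimal gland showed both the genes raised in males and genes that differ between wild type sexes. Ddc was at least 366-fold lower in females (−8.52 ± 0.35, adjusted p = 3.35e-11), and Nmu (−6.92 ± 0.30), Klk1b27 (−6.82 ± 0.43), Klk1b24 (−5.73 ± 0.29), Smr2 (−5.05 ± 0.41) and Klk1b21 (−4.11 ± 0.47) were lower as well. Pnliprp1 was at least 114-fold higher in females (6.83 ± 1.01, adjusted p = 0.000206), although its level varied widely among the knockout female pools (9.17 ± 3.54, mean ± SD). Asgr1 was at least 41.3-fold higher (5.37 ± 0.30, adjusted p = 1.25e-09) and B4galt1 17.3-fold higher (4.12 ± 0.29, adjusted p = 3.21e-08).

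Other genes higher in knockout females were Arg2 (3.62 ± 0.45), Mug1 (3.45 ± 0.35), Cuzd1 (3.13 ± 0.43), Plagl1 (2.65 ± 0.25), Psat1 (2.44 ± 0.22) and Cyp39a1 (2.28 ± 0.19), and others lower were the prostaglandin D synthase gene Ptgds (−3.24 ± 0.28) and Sgk3 (−4.31 ± 0.29), Acsbg1 (−4.04 ± 0.36), Tspan6 (−3.80 ± 0.28) and Clock (−2.70 ± 0.33). Some genes of immune lists were lower in knockout females than in knockout males. Macrophage and dendritic cell genes had 6 of 25 members lower, Csf1r (−1.37 ± 0.24), Lyz2 (−0.90 ± 0.18) and C1qb (−1.07 ± 0.22) among them, and 12 when adjusted over the list alone. Camera gave 2.55e-09 as adjusted p (0.308 with an estimated correlation). Lower too were 4 of 16 cytokines, such as Ccl8 (−2.32 ± 0.29) and Ccl9 (−1.32 ± 0.22), or 7 with 1 higher when adjusted over the list alone. Camera gave 0.000482 as adjusted p (0.251 with an estimated correlation). The interferon-stimulated genes Oas1a (−2.01 ± 0.30) and Oasl2 (−1.26 ± 0.34) were among 3 of 17 lower, 4 when adjusted over the list alone. Camera gave 7.55e-05 as adjusted p (0.207 with an estimated correlation). Complement and acute phase genes had 4 of 9 lower, with Lcn2 (−3.42 ± 0.27) and Serping1 (−1.02 ± 0.20), and 1 higher, as when adjusted over the list alone. Camera gave 0.000385 as adjusted p (0.186 with an estimated correlation). B2m (−1.44 ± 0.21) was the 1 class I gene of 10 that was lower, 2 when adjusted over the list alone. Camera gave 0.00272 as adjusted p (0.327 with an estimated correlation). Fibroblast genes such as Mfap5 (−1.47 ± 0.26) and Col3a1 (−1.03 ± 0.20) were lower, 4 of 22, or 6 with 1 higher when adjusted over the list alone. Camera gave 0.00144 as adjusted p (0.327 with an estimated correlation). On CodeLink the complement (mean −0.20, adjusted p = 0.586) list did not pass camera. Camera also placed oxidative phosphorylation, ribosomal protein, proteasome, secretory pathway and chaperone genes higher and androgen-responsive, class II, immediate early and cell cycle genes lower (smallest adjusted p = 0.207 with an estimated correlation).

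Of genes between knockout sexes 696 passed 5%, 405 higher and 291 lower in females, with Pnliprp1 and Ddc at the ends, and the median of all genes was shifted by 0.105. Quantile normalization gave 346 higher and 403 lower, and the 40th percentile pseudocount 259 higher and 350 lower. On CodeLink 389 of 492 genes had the same sign and 514 passed, 138 higher and 376 lower in females, a balance opposite to that on Affymetrix. The count was 352 without replicate 1 and 400 without replicate 2 of the knockout females, and 396 without replicate 1 of the knockout males.

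In the meibomian glands of females few genes passed for the knockout, while 1253 had an unadjusted p under 0.05 (372 expected without any effect) and the median of all genes was shifted by −0.0912. Akr1c18, a hydroxysteroid dehydrogenase, fell 2.79-fold (−1.48 ± 0.17, adjusted p = 0.000464), and by a difference of −1.32 on CodeLink, the only gene that passed on both array types. The subunit gene of the pyruvate dehydrogenase complex Dlat fell by a log2 difference of −0.70 ± 0.10 (adjusted p = 0.00918) and the water channel gene Aqp5 by −0.69 ± 0.14 (adjusted p = 0.0330). Pofut2, which adds fucose to proteins, rose by 0.82 ± 0.16 (adjusted p = 0.0316). Smaller decreases were those of Arih2 (−0.80 ± 0.09), Rab27b (−0.73 ± 0.15), Dus1l (−0.73 ± 0.13), Mtarc2 (−0.62 ± 0.13), Lonp2 (−0.56 ± 0.10) and Mccc1 (−0.52 ± 0.11), where Arih2 differed by −0.03 on CodeLink. Without the CodeLink array of wild type female replicate 3, which stands apart, Arih2 and Lonp2 were positive there, at 0.0708 and 0.12. Dlat lies among the 100 tested genes on either side of the aromatase gene.

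Lists of genes leaned in small steps in meibomian glands of knockout females, and few members passed. Macrophage and dendritic cell genes had 26 of 28 positive, with C1qb (0.78 ± 0.21) and C1qa (0.41 ± 0.15) as examples, and 0 passed over all genes and 1 when adjusted over the list alone. Camera gave 5.56e-11 as adjusted p, and adjusted p = 0.649 with an estimated correlation. Hair keratin genes, markers of hair follicles of the eyelid, had 21 of 22 positive, Tchh (0.77 ± 0.25) with the smallest p, and none passed over all genes or adjusted over the list alone. Camera gave 1.03e-08 as adjusted p, and adjusted p = 0.649 with an estimated correlation. All 9 sex steroid genes tested were negative, Akr1c18 fell, and 2 fell when adjusted over the list alone. Camera gave 0.0142 as adjusted p, and adjusted p = 0.649 with an estimated correlation. Lipid synthesis genes, the main product line of this gland, had 23 of 28 negative differences, Hacd3 (−0.51 ± 0.12), Thrsp (−0.76 ± 0.23) and Elovl6 (−0.36 ± 0.12) among them, where none passed over all genes and 4 fell when adjusted over the list alone. Camera gave 0.0190 as adjusted p, and adjusted p = 0.811 with an estimated correlation. The mean of −0.21 was 0.0107 on CodeLink without the array that stands apart. Secretory pathway genes had a mean of −0.18, none passing over all genes and 4 falling when adjusted over the list alone. Camera gave 0.00571 as adjusted p, and adjusted p = 0.811 with an estimated correlation. After quantile normalization none of these 3 downward lists passed camera, with means of −0.209 for sex steroid genes (adjusted p = 0.0776), −0.0818 for lipid synthesis (0.118) and −0.0639 for the secretory pathway (0.155). Proteasome genes had 31 of 32 and oxidative phosphorylation genes 58 of 60 negative (camera adjusted p = 0.0127 and 0.0130, and adjusted p = 0.883 and 0.883 with an estimated correlation), and these lists did not pass after quantile normalization either (0.155 and 0.325). None of the 5 downward lists passed on CodeLink. The median of all genes went down too, so a general shift is not excluded. Cytokine, class II and complement genes leaned higher (camera adjusted p = 0.00272, 0.00571 and 0.0127, and adjusted p = 0.649, 0.649 and 0.811 with an estimated correlation). Of these only cytokine genes did not pass on CodeLink. In these 3, the proteasome and the oxidative phosphorylation list 0 members passed over all genes or adjusted over the list alone.

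In meibomian glands of females 29 genes passed 5%, 11 higher and 18 lower, Akr1c18 among the 6 that changed by a factor of 2 or more, and quantile normalization gave 9 and 5. The sign was the same on CodeLink for 11 of 19 genes, and 3 passed there, Akr1c18, Mcam and Cryab, all lower, Mcam and Cryab chosen after their values were seen. Mcam and Cryab lie among the 100 tested genes on either side of the aromatase gene. The count was 2 without replicate 1 and 2 without replicate 3 of the knockout females, 5 and 9 without replicates 1 and 3 of the wild type females and 18 without replicate 2 of the wild type males.

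In the meibomian glands of males no gene passed 5% by limma on Affymetrix, while 1211 had an unadjusted p under 0.05 (372 expected without any effect) and 1 passed on CodeLink, the chaperone gene Cryab, chosen after its value was seen. Genes that did not pass but differed by at least 1 log2 unit with the same sign on CodeLink included Zfp958 (1.19 ± 0.29), the cytochrome P450 gene Cyp2e1 (−1.03 ± 0.23) and the immediate early gene Nr4a1 (−1.57 ± 0.54). Immediate early genes, which respond within minutes to handling of tissue, leaned lower in knockouts, 18 of 22 negative, with Fos (−1.55 ± 0.35), Zfp36 (−0.51 ± 0.12) and Dusp1 (−0.83 ± 0.22), where none passed over all genes and 9 fell when adjusted over the list alone. Camera gave 3.86e-09 as adjusted p (0.464 with an estimated correlation). Melanocyte genes leaned higher, with Tyrp1 (0.67 ± 0.13) and Tyr (0.57 ± 0.20) as the 2 of 5 that passed when adjusted over the list alone and 0 over all genes. Camera gave 0.00938 as adjusted p (0.627 with an estimated correlation). Macrophage genes had 25 of 28 positive and 0 passed over all genes or adjusted over the list alone. Camera gave 0.00955 as adjusted p (0.995 with an estimated correlation). Estrogen-responsive genes of the uterus had 8 of 12 negative, where 0 passed over all genes and 3 fell when adjusted over the list alone. Camera gave 0.0314 as adjusted p (0.351 with an estimated correlation). On CodeLink the macrophage (mean 0.11, adjusted p = 0.380) list did not pass camera. Camera also placed interferon-stimulated genes higher and myoepithelial and clock genes lower (smallest adjusted p = 0.351 with an estimated correlation). Without replicate 3 of the knockout males the count was 120, without replicate 2 of the knockout females 1 and without replicate 3 of the wild type females 3.

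No meibomian gene passed 5% for a difference of the knockout effects between the sexes by limma, while 1044 genes on Affymetrix (372 expected without any effect) and 512 on CodeLink had an unadjusted p under 0.05 and 0 passed on CodeLink. The median of all genes was shifted by −0.122. Without replicate 1 of the knockout males 12 genes passed. Genes that did not pass, with differences of at least 1 log2 unit, were S100a8 (1.51 ± 0.52), Tnfrsf12a (1.08 ± 0.23), Osgin1 (1.06 ± 0.23), Nuf2 (−1.07 ± 0.31) and Tbc1d23 (−1.05 ± 0.25). Immediate early genes leaned toward females, 19 of 22 positive, with Gadd45b (0.89 ± 0.25) and Zfp36 (0.52 ± 0.18), and none passed over all genes or adjusted over the list alone. Camera gave 2.02e-07 as adjusted p (0.472 with an estimated correlation). Melanocyte genes leaned toward males, with Tyrp1 at −0.85 ± 0.19, none over all genes and 1 when adjusted over the list alone. Camera gave 0.0113 as adjusted p (0.485 with an estimated correlation). Camera also placed hair keratin, class II, plasma cell, cytokine, endothelial, macrophage, complement and estrogen-responsive genes higher and proteasome, oxidative phosphorylation, secretory pathway and interferon-stimulated genes lower (smallest adjusted p = 0.472 with an estimated correlation).

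**Figure D3:**
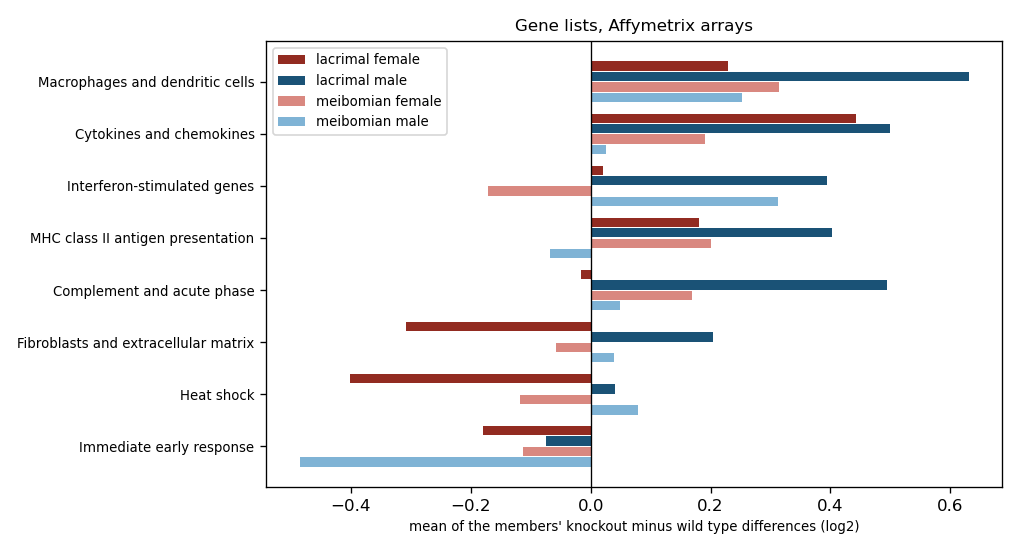
Mean log2 knockout minus wild type difference over the members of 8 gene lists (bars, from 0) in the 4 gland and sex comparisons on Affymetrix. The lacrimal glands of males have the highest bar for macrophage genes, a mean of 0.63.

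Sex differences of the meibomian glands in wild type mice were many but small. Apart from Xist and Eif2s3y, the mast cell protease gene Cpa3 was 2.81-fold higher in females (1.49 ± 0.17, adjusted p = 0.000183) and Akr1c18 2.18-fold higher (1.12 ± 0.17, adjusted p = 0.00205). The cornified envelope gene Sprr3 was 2.34-fold lower in females (−1.22 ± 0.27, adjusted p = 0.0148) and the membrane mucin gene Muc4 2.28-fold lower (−1.19 ± 0.16, adjusted p = 0.00109). Glucocorticoid-regulated Tsc22d3 (0.87 ± 0.18) and Cebpd (1.02 ± 0.18), the clock output gene Dbp (0.93 ± 0.21), the lipolysis inhibitor gene G0s2 (0.85 ± 0.24) and Fmo1 (0.99 ± 0.18), Sult1c1 (0.94 ± 0.13), Lum (0.96 ± 0.23) and Mgp (0.84 ± 0.19) were higher in females, and Srsf5 (−1.15 ± 0.21), Ogt (−0.94 ± 0.15), Snrnp70 (−0.86 ± 0.12), Brd2 (−0.82 ± 0.17), Mafg (−0.85 ± 0.16) and Il1f9 (−0.83 ± 0.16) lower.

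Markers of cell types around the meibomian glands moved with sex in wild type mice. Skeletal muscle genes had 12 of 26 members lower in females, such as Ttn (−0.83 ± 0.14), Pygm (−0.55 ± 0.10), Ryr1 (−0.51 ± 0.10) and Pvalb (−0.57 ± 0.12), and 16 when adjusted over the list alone. Camera gave 6.32e-13 as adjusted p (0.109 with an estimated correlation). Fibroblast and matrix genes had 15 of 26 higher in females, with Postn (0.68 ± 0.14), Igfbp4 (0.50 ± 0.11) and Col5a2 (0.55 ± 0.12), and 21 when adjusted over the list alone. Camera gave 6.08e-10 as adjusted p (0.433 with an estimated correlation). Macrophage genes had 10 of 28 higher, with Laptm5 (0.75 ± 0.18) and C1qb (0.83 ± 0.21), or 20 with 1 lower when adjusted over the list alone. Camera gave 0.000181 as adjusted p (0.999 with an estimated correlation). On CodeLink the macrophage (mean 0.27, adjusted p = 0.137) list did not pass camera. Camera also placed oxidative phosphorylation genes higher and hair keratin and immediate early genes lower (smallest adjusted p = 0.999 with an estimated correlation). Over all genes 635 passed 5%, 439 higher in females, Cpa3 first after Xist, and 196 lower, and quantile normalization gave 193 higher and 263 lower. CodeLink had the same sign for 346 of 398 genes, and 566 passed there. Leaving out replicate 1, 2 or 3 of the wild type females gave 383, 165 and 341 genes, and leaving out replicate 1 or 2 of the wild type males 338 and 70. Replicate 2 of the wild type females had the lowest median Affymetrix signal of the gland, 35.5.

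Between knockout females and males the meibomian glands differed as well. Tsc22d3, a glucocorticoid-induced gene, was 2.60-fold higher in females (1.38 ± 0.18, adjusted p = 0.00118) and Cebpd 2.33-fold higher (1.22 ± 0.18, adjusted p = 0.00193). Higher in females too were Ccn3 (1.13 ± 0.17), Ccl9 (1.10 ± 0.27), Adipoq (1.08 ± 0.21), Mgp (1.07 ± 0.19) and Pltp (0.99 ± 0.16), and lower Rpl12 (−1.26 ± 0.18), Srsf5 (−1.21 ± 0.21), Il18r1 (−1.01 ± 0.29), Clk4 (−1.01 ± 0.18), Sprr3 (−0.94 ± 0.27) and Cyp2b19 (−0.87 ± 0.11). Skeletal muscle genes had 13 of 26 lower in females, with Ttn (−0.87 ± 0.14), Tnnt3 (−0.62 ± 0.11) and Ryr1 (−0.53 ± 0.10), or 20 with 1 higher when adjusted over the list alone. Camera gave 8.99e-10 as adjusted p (0.133 with an estimated correlation). Fibroblast genes had 9 of 26 higher, with Col14a1 (0.86 ± 0.12) and Col6a2 (0.73 ± 0.15), and 14 when adjusted over the list alone. Camera gave 9.18e-12 as adjusted p (0.141 with an estimated correlation). Macrophage genes had 6 of 28 higher, with Laptm5 (1.01 ± 0.18), C1qb (1.08 ± 0.21) and Tyrobp (1.00 ± 0.25), and 19 when adjusted over the list alone. Camera gave 1.47e-11 as adjusted p (0.347 with an estimated correlation). The endothelial genes Esam (0.86 ± 0.16), Plvap (0.96 ± 0.22) and Vwf (0.66 ± 0.18) were higher, 6 of 13, or 8 with 1 lower when adjusted over the list alone. Camera gave 3.68e-06 as adjusted p (0.0931 with an estimated correlation). Class II genes H2-Ab1 (0.76 ± 0.15), Cd74 (0.65 ± 0.14) and H2-DMa (0.75 ± 0.17) were higher, 3 of 7, and 6 when adjusted over the list alone. Camera gave 1.41e-05 as adjusted p (0.193 with an estimated correlation). Camera also placed cytokine, complement, immediate early and plasma cell genes higher and proteasome, cell cycle, interferon-stimulated and cholesterol synthesis genes lower (smallest adjusted p = 0.141 with an estimated correlation).

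Between the knockout sexes 513 meibomian genes passed 5%, 209 higher in females, such as Tsc22d3, and 304 lower, and quantile normalization gave 305 higher and 262 lower. On CodeLink 298 of 319 had the same sign and 291 passed. The count was 170 without replicate 1 and 60 without replicate 3 of the knockout females and 193 without replicate 2 of the knockout males.

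The female knockout effect differed between the glands, and by the naming rule only genes with the same sign on CodeLink are named. The difference, lacrimal minus meibomian effect, was 2.82 ± 0.63 for the mucin sialyltransferase gene St6galnac1 and −2.42 ± 0.23 for Slc39a8. It was positive for Wwox (2.15 ± 0.24), Bok (2.15 ± 0.26), Fut8 (2.13 ± 0.38), Pmvk (2.12 ± 0.30) and Dnase1l2 (1.99 ± 0.38) and negative for Ddr1 (−2.23 ± 0.43), Abcb1a (−1.75 ± 0.42), Khdrbs3 (−1.62 ± 0.31), Hmgn3 (−1.58 ± 0.22) and Glul (−1.56 ± 0.26). Camera also placed secretory pathway genes higher (adjusted p = 0.872 with an estimated correlation). In females 229 of 6577 genes expressed in both glands passed 5%, 130 positive and 99 negative, 133 of 149 with the same sign on CodeLink, where 101 passed. The balance turned with the pseudocount, with 186 positive and 83 negative at the 5th and 81 positive and 171 negative at the 40th percentile. Without replicate 3 of the lacrimal knockout females the count was 128, without meibomian knockout female replicates 1 and 3 in turn 130 and 118, and without replicate 3 of the meibomian wild type females 147.

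In males the effect differed between the glands for Nmu (7.34 ± 0.32), Smr2 (4.07 ± 0.57), Tspan6 (3.34 ± 0.33), Dpysl3 (2.28 ± 0.22), Acsbg1 (2.22 ± 0.36) and Dusp1 (1.79 ± 0.41), more positive in the lacrimal gland, and for B4galt1 (−2.99 ± 0.34), Shisa2 (−2.11 ± 0.37), Cmya5 (−1.63 ± 0.32), Plagl1 (−1.54 ± 0.31), Tspan12 (−1.51 ± 0.34) and Sat1 (−1.28 ± 0.23), more negative there. Il18 (1.69 ± 0.26) and Cxcl16 (1.22 ± 0.30) were the 2 of 12 cytokines with a more positive lacrimal effect, 2 when adjusted over the list alone. Camera gave 0.000145 as adjusted p (0.331 with an estimated correlation). Macrophage genes had 23 of 25 positive and none passed over all genes or adjusted over the list alone. Camera gave 4.70e-05 as adjusted p (0.337 with an estimated correlation). Lcn2 (1.69 ± 0.41) was the 1 complement and acute phase gene of 8 to pass, while 2 were higher and 1 lower when adjusted over the list alone. Camera gave 0.00351 as adjusted p (0.331 with an estimated correlation). Camera also placed immediate early, class II, class I, myoepithelial, plasma cell, cell cycle, estrogen-responsive and lipid synthesis genes higher and chaperone genes lower (smallest adjusted p = 0.331 with an estimated correlation). In males 69 genes passed 5%, 36 positive and 33 negative, 35 of 39 with the same sign on CodeLink, where 35 passed. The count was 41 and 120 without lacrimal knockout male replicates 1 and 2, 39 without lacrimal wild type male replicate 3, 44 without meibomian knockout male replicate 1, and 36 and 44 without meibomian wild type male replicates 2 and 3. Gland and, by the CodeLink labels, RNA extraction differed together, so only effects within a gland were compared.

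Effects were correlated across genes for 5 pairs of comparisons, with genes not independent replicates. The female and male knockout effects, which share no array, correlated at r = 0.157 (rho = 0.161) in lacrimal and 0.257 (0.182) in meibomian glands. Across the glands the female effects gave r = 0.000706 (−0.0321), the male effects 0.0750 (0.0834) and the wild type sex differences 0.0990 (0.00765). In meibomian glands the female knockout effect and the male-minus-female difference gave r = 0.169 (0.241 simulated) and a covariance of 0.0111 (0.0132 simulated), and in males r = −0.395 (−0.242) and −0.0264 (−0.0132). On CodeLink r was −0.306 (−0.241) in males and 0.521 (0.243) in females, where unshared arrays gave both signs on each type.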

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

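The tests of explanations and the splits of the arrays in this part were chosen only after the results they address had been seen, while the differences of effects between sexes and between glands were planned. The differences of effects are log2 values that passed 5% by limma on Affymetrix.

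The lacrimal knockout effect differed between the sexes for 123 genes. The female minus male difference was positive for B4galt1 (3.51), B4galt6 (3.22), Cuzd1 (5.53), Cyp2j13 (5.32), Ly6f (6.54), Mug1 (3.33) and Prol1 (3.53), and negative for Cp (−1.57), Ddc (−7.24), Klk1b21 (−4.12), Klk1b24 (−4.08), Klk1b27 (−6.67), Lcn2 (−2.02), Mt1 (−1.41), Nmu (−6.56) and Smr2 (−4.36).

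The female knockout effect differed between the glands for 229 genes. The lacrimal minus meibomian difference was positive for Bok (2.15), Dnase1l2 (1.99), Fut8 (2.13), Pmvk (2.12), St6galnac1 (2.82) and Wwox (2.15), and negative for Abcb1a (−1.75), Ddr1 (−2.23), Glul (−1.56), Hmgn3 (−1.58), Khdrbs3 (−1.62) and Slc39a8 (−2.42). The male effect differed for 69 genes, positive for Acsbg1 (2.22), Cxcl16 (1.22), Dpysl3 (2.28), Dusp1 (1.79), Il18 (1.69), Lcn2 (1.69), Nmu (7.34), Smr2 (4.07) and Tspan6 (3.34), and negative for B4galt1 (−2.99), Cmya5 (−1.63), Plagl1 (−1.54), Sat1 (−1.28), Shisa2 (−2.11) and Tspan12 (−1.51).

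Genes raised in lacrimal glands of knockout males include salivary gland genes such as Klk1b27 and Smr2. Carry-over of salivary tissue, scaling and cross-hybridisation were therefore weighed for the 7 genes named by rule that rose by at least 3 log2 units. Carry-over would bring salivary markers along, but the salivary score was lower in knockout than in wild type males (−1.78), below every wild type male array on 2 of the 3 knockout male arrays, and after quantile normalization the smallest difference of the 7 genes was still 3.65, which argues against the scaling. Probes that bind related kallikreins stay open for the Klk1b genes, since 7 of 8 Klk1b genes were at least 1 log2 unit higher while the Klk1 probe sets differed by 0.21, −0.27 and 0.05, and Ddc, Nmu, Smr2 and Tspan6 are not kallikreins. On CodeLink 5 of the 7 passed and the smallest log2 difference was 0.59, but the same sign there was a condition for choosing them. A candidate explanation is a response of these genes to the changed hormones of knockout males, which was not tested.

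The lacrimal knockout effect in females followed the direction of males, with a slope of 57.0% on the sex difference across genes. Scaling of the dimmer knockout female arrays is argued against by the slope after quantile normalization, 53.8%. Shared wild type arrays as the whole cause are argued against by the lowest correlation without sharing, 0.454 on Affymetrix and 0.315 on CodeLink. The rank correlation went down to 0.0578 on CodeLink. Salivary carry-over is argued against by the slope with the salivary score removed, 57.4%. The slope itself was 56.1% on CodeLink and ran from 50.2 to 65.7% with single arrays left out. In males it was 24.3% (33.2% on CodeLink), and in meibomian glands of females −3.48% on Affymetrix and 31.5% on CodeLink. With wild type arrays not shared, r there ran from −0.162 to 0.12 on Affymetrix and −0.182 to 0.222 on CodeLink. No direction can be read there. The lacrimal gland of knockout females may thus shift toward the male pattern, a hypothesis found and tested on the same data.

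Genes near the aromatase gene changed alike in knockouts of both sexes, counted over the 100 tested genes on each side with a limma p under 0.01 in each sex. In lacrimal glands these were 2% of nearby and 0.678% of other genes on Affymetrix (Fisher's exact test, two-sided, adjusted over 4 tests, p = 0.0536) and 1.5 against 0.316% on CodeLink (exact p = 0.0425), and in meibomian glands 3.5 against 0.36% (exact p = 4.35e-05) and 3 against 0.063% (exact p = 5.69e-07). DNA linked to the targeted gene may account for this, but it cannot be told apart from regulation, because strains are not stated in the labels and neighbouring genes are not independent. Variants under a probe are argued against for 3 changes seen on both array types, Atm (−1.34 in females and −1.35 in males) and Il18 (1.20 and 1.68) in lacrimal and Dlat (−0.70 and −0.44) in meibomian glands, and stay open for 3 measured on CodeLink without the same change. On CodeLink, Cryab fell in both glands and sexes (lacrimal females and males −1.79 and −1.80, meibomian −1.74 and −1.65), while on Affymetrix the values were −1.31, −0.44, −0.26 and −0.31 and only the first passed, so variants under a probe stay open for it.

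Splits of the arrays into other groups gave the following counts. With 3 arrays against 3 the 10 splits are too few for a share under 0.05, and the real counts and highest others were 307 and 3 for lacrimal females, 136 and 1 for lacrimal males, 1063 and 2 between wild type and 696 and 6 between knockout lacrimal sexes. In meibomian glands they were 29 and 0 for females, 0 and 0 for males, where all 10 splits gave 0, and 635 and 0 and 513 and 0 between the sexes of wild types and knockouts. In the other 7 designs of 3 against 3 only the real split was as large. For the differences of effects 100 splits were drawn, among them the exchange of all genotype labels within 1 sex or gland, which tests the sum of the 2 effects in place of their difference and gave the highest other count each time. For the lacrimal difference 3 of 100 splits were as large as the real 123, namely the real one, the exchange (313) and an ordinary split (128). An ordinary split mixes knockout and wild type arrays, so the knockout effects themselves add to the spread within its groups. This lowers its count with or without a difference of effects, so a small share of such splits cannot exclude chance. For the meibomian difference the real count was 0, which any split equals, so the splits test nothing there (exchange 119, highest ordinary split 6). For the difference between the glands 2 of 100 splits were as large as 229 in females (exchange 280), and the highest ordinary split, 224, came close. In males 5 of 100 were as large as 69 (exchange 120, highest ordinary split 84). Chance is not excluded in either sex, for the same reason.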

How the results depend on the processing

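The alternatives CodeLink with quantile normalization or a replicate block, the salivary score as a covariate and the fits less the arrays that stand apart were chosen after seeing the data, and the others were planned. Of 279 results for named genes, 159 kept their direction and side of the threshold in every alternative run. Over 7392 recomputed values 704 lost the call, 3 gained it and 8 reversed. The rule that the largest changes have the same sign on CodeLink keeps the last number low. Of 61 list results 17 kept both, and over 1551 values 190 lost the call and 8 reversed. Counts of genes were within 1.5 times in 257 of 341 recomputed values. The 5th percentile pseudocount and the salivary covariate moved no count by over 1.5 times. Why the values moved is open, and the cause was not tested. On CodeLink between 35.9 and 62.6% of spots per array carried the flag G, and on Affymetrix the pseudocount pulls the changes of dim genes toward 0.

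Leaving out each array in turn gave counts of 151 to 412 for lacrimal females, 61 to 155 for lacrimal males, 587 to 1405 for lacrimal wild type sexes, 352 to 814 for lacrimal knockout sexes, 90 to 179 for the lacrimal difference of effects, 2 to 37 for meibomian females, 0 to 120 for meibomian males, 70 to 774 for meibomian wild type sexes, 60 to 560 for meibomian knockout sexes, 0 to 12 for the meibomian difference of effects, 118 to 336 for the gland difference in females and 36 to 120 for the gland difference in males. With 1 array left out a group holds 2, and the fit pools the spread over the groups.

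Counts that moved by over 1.5 times were as follows. CodeLink arrays gave 149 for lacrimal females, 61 for lacrimal males, 463 for lacrimal wild type sexes, 74 for the lacrimal difference of effects, 3 for meibomian females, 1 for meibomian males, 291 for meibomian knockout sexes, 101 for the gland difference in females and 35 for the gland difference in males. With quantile normalization CodeLink gave 167 for lacrimal females, 79 for lacrimal males, 513 for lacrimal wild type sexes, 3 for meibomian females, 1 for meibomian males and 135 for the gland difference in females, and less its meibomian array that stands apart 2 for meibomian females, 1 for meibomian males, 83 for the gland difference in females and 41 for the gland difference in males. The mean of both array types gave 578 for lacrimal wild type sexes, 433 for lacrimal knockout sexes, 3 for meibomian females, 1 for meibomian males, 136 for the gland difference in females and 37 for the gland difference in males. Fitting only the groups compared gave 85 for lacrimal males, 16 for meibomian females, 1 for meibomian males, 304 for meibomian knockout sexes and 36 for the gland difference in males. Less both meibomian arrays that stand apart the counts were 244 for meibomian wild type sexes, 236 for meibomian knockout sexes and 34 for the gland difference in males. Every probe set on its own gave 72 for meibomian females and 3 for meibomian males, no filter 3 for meibomian males, the top 40% of genes 44 for the gland difference in males, no intensity trend 15 for meibomian females, quantile normalization 14 for meibomian females and the 40th percentile pseudocount 502 for lacrimal females. A fit of only the groups compared does not apply to the differences of effects between the sexes, which use every group of a gland.

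Reversed values were few. Kdm5d turned to 0.43 between wild type and 0.55 between knockout lacrimal sexes on CodeLink, with or without the block, and to 0.34 and 0.54 with quantile normalization there. Oxidative phosphorylation genes between wild type lacrimal sexes turned to a mean of −0.0415 on CodeLink, with or without the block, and −0.0206 with quantile normalization. Without the CodeLink array that stands apart, Arih2 turned to 0.0708, Lonp2 to 0.12 and lipid synthesis genes to 0.0107 in meibomian females. Camera also turned there for oxidative phosphorylation genes on CodeLink (mean −0.0124 with or without the block, 0.0359 with quantile normalization) and for proteasome genes (0.0078 with quantile normalization). The cause was not tested.

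Replicate numbers did not pair the pools across groups by the rule that every same-number pair has deviations correlated over 0.1. Of 18 same-number pairs across groups, 6 lacrimal and 9 meibomian Affymetrix pairs and 10 and 5 CodeLink pairs passed 0.1, with values from −0.19 to 0.25 on Affymetrix, −0.473 to 0.707 on lacrimal and −0.31 to 0.24 on meibomian CodeLink arrays. A processing step shared by number is thus not excluded for lacrimal CodeLink arrays. On Affymetrix a fit with a replicate block changed no count by over 1.5 times, with 318 genes in lacrimal females, 136 in lacrimal males, 1122 and 733 between lacrimal sexes of wild types and knockouts and 128 for the lacrimal difference of effects. It gave 33 in meibomian females, 0 in meibomian males, 761 and 598 between meibomian sexes, 0 for the meibomian difference of effects, and 248 and 72 between the glands in females and males. Of the results for named genes 5 lost the call under the block. On CodeLink the replicate block gave 213 genes in lacrimal females (149 without it), 84 in lacrimal males (61), 579 and 679 between lacrimal sexes (463 and 514) and 135 for the lacrimal difference of effects (74). It gave 2 and 1 in meibomian females and males, 601 and 259 between meibomian sexes, 0 for the meibomian difference, and 122 and 43 between the glands.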

Other observations

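Single genes of steroid metabolism changed in lacrimal glands beyond those named by rule, and Hsd17b11, Clu, Fdft1, Arntl, Per1 and Bhlhe40 as well as the comparisons given here for Akr1c18 were chosen after their values were seen. Hsd17b11, a hydroxysteroid dehydrogenase, rose in knockout females by 2.67 ± 0.19 (limma, adjusted p = 6.58e-08) and was lower in wild type females than males by −3.10 ± 0.19 (adjusted p = 3.05e-09). Akr1c18 fell in lacrimal glands of knockout females, by −1.08 ± 0.16 (adjusted p = 0.000617), as it did in meibomian glands. Of 8 sex steroid genes tested in lacrimal glands of females 1 rose and 1 fell, or 2 and 2 when adjusted over the list alone, and camera gave an adjusted p = 0.508. Clusterin (Clu) rose in knockout females by 0.89 ± 0.18 and was the only estrogen-responsive gene of the uterus, of 9 tested, that passed there. In the list of cholesterol synthesis Pmvk rose and squalene synthase (Fdft1) fell by −1.52 ± 0.30 in knockout females, and Fdft1 was higher in wild type females than males by 2.73 ± 0.30.

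Clock genes differed between the sexes of wild type lacrimal glands, where Arntl (−1.26 ± 0.34), Clock (−1.16 ± 0.33) and Bhlhe40 (−1.47 ± 0.33) were lower and Per1 (1.07 ± 0.19) was higher in females. Of 13 clock genes tested 3 were higher and 3 lower, or 6 and 3 when adjusted over the list alone, and camera gave an adjusted p = 0.691.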
